A study of Mus musculus with 6 samples.

How the data were processed

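The series holds 6 single-colour Agilent mouse expression arrays, 3 of C4HD primary cultures transfected with pre-miR-Control and 3 of cultures transfected with pre-miR-16, each a biological replicate per the labels. Per the labels' protocols, total RNA was isolated with the miRVANA PARIS kit 48 h after transfection of 30 nM precursor with siPORT NeoFX, and was labelled with Cy3. Groups were taken from the sample titles and labels only. No reference genome was used here.

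The deposited scanner files give spot intensity values that Agilent Feature Extraction 9.5.3.1 had background-subtracted and corrected for spatial and multiplicative trends within the array, with replacement values for dim spots, per the file headers. These values are not normalized between arrays. The raw mean spot intensity and local background intensity, also per the file headers, were used for 2 alternatives. The deposited series matrix holds log2 values, 1 per probe, whose normalization between arrays is not stated in the labels. Its 6 columns have medians from 6.79 to 6.81 and a lowest value of 5.65. In it the columns of pre-miR-16 replicates 1 and 2 follow each other's scanner file (Spearman 0.968 and 0.971 with their own file, 0.993 and 0.996 with the other), so the scanner files were used, and since both columns belong to the same group the comparison from the matrix is unaffected by the order. No matrix column lacked a sample.

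Values were processed with R 4.3.3, limma 3.58.1 and version 1.17.8 of data.table. Control spots and spots that the scanner software marked as outliers (74 to 113 per array) were left out. Of 43379 remaining spots per array, those of the same probe were averaged on the log2 scale, which gave 41174 probes. Each array's 75th percentile was subtracted. A probe was kept where at least 0.50 of its spots were well above background on all 3 arrays of at least 1 group, and 4 probes with a missing array were left out, which left 23831. Probes were named by RefSeq accession (22951), otherwise by a symbol in the file that matches a current one (6659), otherwise by the name in the file (11564), and for each gene the probe with the highest mean was tested, which gave 16702 genes. Coordinates are those of the files (mm7, NCBI35), and the gene table, on a later build, served for names only.

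Groups were compared with lmFit and eBayes in limma, without intensity trend, and p-values were adjusted by Benjamini and Hochberg over all genes, with genes called at an adjusted p under 0.05. These p-values weigh the difference between the groups against the spread among arrays of the same group, moderated across genes. They speak for these 6 samples only. With 3 arrays per group an exact test of group labels could not give p under 0.10. Where no probe of a gene was well above background on any array of 1 group, its change is printed as a lower bound of the fold. This bound holds for the processed signal only, and another background correction can give less. For gene lists the number of called genes is given over all genes and with the adjustment over the list alone. Lists with at least 5 measured genes were tested with limma's camera (preset inter-gene correlation of 0.01), with camera with an estimated correlation and with fry, adjusted over the 23 lists tested. Median changes of lists were also taken within slides 1 and 2.

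The 26 gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, except where stated. The genes named are the 12 with the largest fall and the 12 with the largest rise among called genes with no overlap between the groups and an established symbol, up to 4 genes per list with the smallest p, the study-named targets, the host genes of miR-16 and the housekeeping genes. Results for some genes that this rule selects are not reported here, and they are left out of the counts of named genes under the alternatives. A further 9 lists were written after the first results were seen. The study-named targets and the reported miR-16 targets were recalled from the literature and not taken from the labels.

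The alternatives were quantile normalization, median centring, normexp background correction (offset 50) followed by the 75th percentile or by quantile normalization, the series matrix values, 2 other filters on dim probes, outlier spots kept, the mean of a gene's probes, eBayes with trend and robust, array weights, replicate number or slide as a block, each array left out in turn, and 2 other thresholds. Chosen after seeing the data were scaling on the spike-in probes, slide as a random block and a block that follows the matrix order of replicates. Slide 1 held pre-miR-Control replicate 1 and pre-miR-16 replicate 1, slide 2 held pre-miR-Control replicates 2 and 3 and pre-miR-16 replicate 2, and slide 3 held only pre-miR-16 replicate 3; each slide was scanned in its own session.

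The code was tested on simulated data for 16702 genes with the spread of these arrays: of genes changed by 0.5, 1 and 2 on the log2 scale it recovered 1.49%, 65.7% and 97.0%, with 6 false calls, and of 10 simulated lists it called 1, the 1 that had been shifted. Far fewer genes were changed there than were called in the real comparison, which makes the adjustment stricter in the simulation. Simulated genes varied independently, while the correlation estimated within the G2/M and mitosis list was 0.81. The simulation therefore does not test the list calls under such correlation. Each of the 10 ways to split the 6 arrays into groups of 3 was also tested. A planned test of miR-16 seed sites in 3' UTRs was not run, since no 3' UTR sequences were in the reference used here, and the 60-base probes were searched for the seed match in its place.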

Results

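Primary cultures of C4HD, a mouse mammary tumour that arose in BALB/c females under the progestin medroxyprogesterone acetate and is maintained by transplantation, were transfected with 30 nM of a precursor of the microRNA miR-16 (pre-miR-16) or of a scrambled precursor that forms no known microRNA (pre-miR-Control). RNA was taken after 48 h and hybridised to single-colour Agilent mouse expression arrays. There were 3 biological replicates per condition, 1 array each, so the number of arrays limits the precision. Per the labels' protocols the cultures came from the epithelial fraction of the tumour, after repeated sedimentation to remove fibroblasts. The 75th percentile of the processed signal lay between 625 and 909 units on the 6 arrays, between 57.2% and 64.0% of spots were well above background, and 0 spots were saturated. The comparison asks which transcripts differ when miR-16 is raised in these ErbB-2 positive tumour cells. Levels below are log2 signals relative to the array's 75th percentile, as mean ± SD with n = 3, and changes are log2 fold changes ± SE, pre-miR-16 over pre-miR-Control, from limma with Benjamini-Hochberg adjusted p.

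The pre-miR-16 cultures had far more transcript from genes of macrophages, fibroblasts and inflammatory signalling than the controls, and, with arrays scaled on the 75th percentile, less from luminal keratins and other epithelial genes. Scaled on spike-ins, 3 of 21 luminal markers fell (median -0.12). Adgre1, which encodes the macrophage surface protein F4/80, rose from -4.78 ± 0.71 to 2.77 ± 0.23, a change of 7.55 ± 0.35 (187-fold, adjusted p = 2.72e-05), and was well above background on only 2 of the 3 control arrays. Under normexp background correction the change of Adgre1 was 5.70. Col1a1, a fibrillar collagen of fibroblasts, rose from 2.59 ± 0.02 to 6.52 ± 0.21, a change of 3.94 ± 0.12 (15.3-fold, adjusted p = 1.19e-05). Krt8, a keratin of luminal epithelium, fell from 8.02 ± 0.14 to 6.83 ± 0.07, a change of -1.19 ± 0.11 (adjusted p = 4.29e-04). Ccnj, a cyclin recalled from the literature as a miR-16 target named by this study, fell from -2.71 ± 0.13 to -4.69 ± 0.06, a change of -1.98 ± 0.10 (adjusted p = 4.07e-05).

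**Figure D1:**
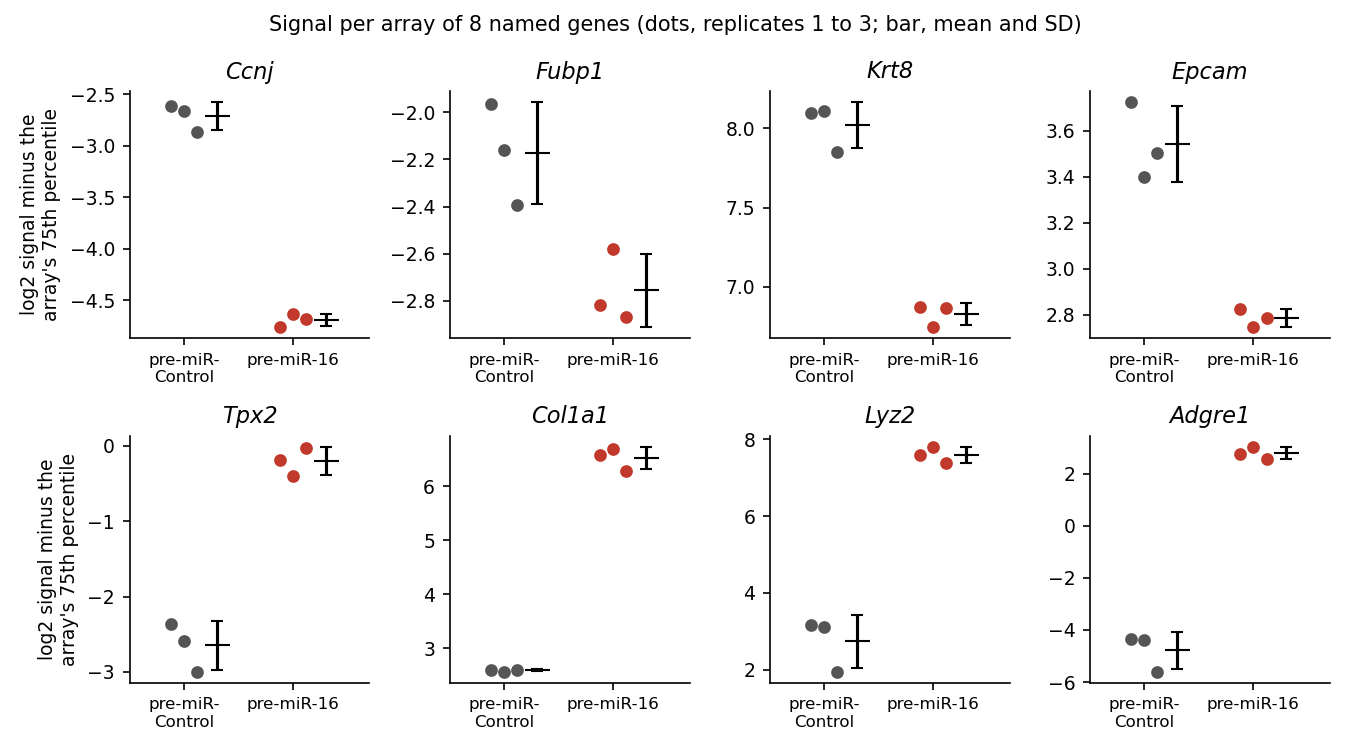
Signal of 8 named genes on each array, as log2 signal minus the array's 75th percentile (vertical axes, which differ between panels), for pre-miR-Control (grey) and pre-miR-16 (red), with the mean and SD of 3 arrays beside the dots. Adgre1 lay between -5.60 and -4.34 on the control arrays and between 2.56 and 3.02 on the pre-miR-16 arrays, and Ccnj between -2.86 and -2.61 against -4.76 to -4.64.

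Of 16702 genes tested, 8197 changed, each called at its brightest probe. Of the 2560 changed genes with 2 or more kept probes, 2281 had all these probes in the same direction. With each array scaled on its 75th percentile, 2664 rose and 5533 fell, so that 32.5% of the calls were rises. The many small falls rest on that scaling: the array's spike-in probes read lower relative to the 75th percentile on the pre-miR-16 arrays, and scaling on them (an alternative chosen after seeing the data) moved every fold change up by 0.38, giving 3672 rises and 1041 falls, or 77.9% rises. The spike-in level relative to the 75th percentile was 3.95, 3.86 and 3.80 on control replicates 1 to 3. It was 3.64, 3.55 and 3.28 on pre-miR-16 replicates 1 to 3, lowest on replicate 3, which was alone on its slide. The other scalings, from median centring to the series matrix values, gave 28.5% to 34.1% rises. How much spike-in RNA each sample received is not given in the sources used here. Large changes were mostly rises, with 954 genes up and 77 down by at least 4-fold where genes not above background in a group are taken at their bound, if they have one (1149 and 108 by the printed differences). The arrays came from 3 slides, of which slides 1 and 2 held both groups. With slide as a block 6009 genes changed (2096 rose, 3913 fell), and 99.98% and 100% of the 8197 genes, which were chosen on the same arrays, had the same direction within slides 1 and 2.

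Of the 12 genes ranked first by the size of their rise, 5 encode chemokines of the Ccl family and 3 serum amyloid proteins. The rank of Ccl3 and Ccl4 is uncertain, as they are known only by a bound. Ccl3 and Ccl4, chemokines made by macrophages, were not well above background on any control array and rose at least 86.2-fold (adjusted p = 1.16e-05) and at least 47.7-fold (adjusted p = 1.09e-04). On the log2 scale Ccl3 and Ccl4 changed by 4.31 and 3.59 under normexp background correction, less than these bounds. The monocyte chemoattractants Ccl2 and Ccl7 rose by 6.60 ± 0.27 and 6.67 ± 0.35, and Ccl6 by 6.79 ± 0.34. Pf4, a platelet and myeloid chemokine, rose by 6.88 ± 0.46, Cd52, a leukocyte surface antigen, by 6.26 ± 0.89 (4.11 under normexp, a background correction with an offset), and Pcsk5, a proprotein convertase, by 6.30 ± 0.39 (4.01). The serum amyloid genes Saa3, Saa2 and Saa1 rose by 8.17 ± 1.18, 7.22 ± 1.63 and 6.75 ± 1.47, with wide errors. Saa3 read 7.46 and 7.30 on pre-miR-16 replicates 1 and 3 but 2.99 on replicate 2, and the call for Saa2 ended with slide as a block (change 5.87, adjusted p = 0.0505).

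The 12 genes ranked first by the size of their fall had varied functions, and 5 of them are known only by a bound. Ptn, which encodes the growth factor pleiotrophin, fell by 4.86 on the log2 scale with an SE of 0.76 (adjusted p = 0.00341), and changed by -3.45 under normexp. It was well above background on 2 of 3 pre-miR-16 arrays and read -5.10, -2.57 and -5.38 on pre-miR-16 replicates 1, 2 and 3. Elf5, a transcription factor of the mammary alveolar lineage, fell from -0.57 ± 0.04 to -4.73 ± 0.88, a change of -4.16 ± 0.41 (adjusted p = 6.44e-04), and was well above background on 1 of 3 pre-miR-16 arrays. Upb1, Plppr4 and Cdx2 changed by -4.03 ± 0.57, -3.80 ± 0.60 and -3.18 ± 0.59. Each was well above background on 1 of 3 pre-miR-16 arrays, and under normexp they changed by -1.95, -1.97 and -1.49. Those known by a bound, Ankrd34c, Lce1c, Tdrd12, Pinlyp and L3mbtl4, were not well above background on any pre-miR-16 array, so that their rank is uncertain, and fell at least 7.59-fold, 7.02-fold, 4.46-fold, 4.44-fold and 2.54-fold. Sprr1a and Cd200r3 changed by -3.70 ± 0.92 and -3.21 ± 0.88, and with slide as a block neither was called (-2.91, adjusted p = 0.0703, and -2.39, adjusted p = 0.0727), nor without several of the single arrays. Many of these genes were dim: under normexp, 36 of the 107 named and called genes had a log2 change over 1.5 times smaller, among them Elf5 (-2.57), Ccl3 (4.31) and Ccnj (-1.07). Bounds hold for the processed signal only, and normexp can give less, as for Reck (0.71). Ccl3 changed by 4.31 under normexp against a log2 bound of 6.43, and Ankrd34c by -1.74 against -2.92.

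Genes of fibroblasts and the extracellular matrix rose nearly as a block. Of 20 measured, 19 rose and 0 fell, 19 also when adjusted over the list alone, with a median change of 4.06 (interquartile range 3.08 to 4.29). Col1a2, Col5a1 and Pdgfrb, the last a receptor of mesenchymal cells, rose by 4.16 ± 0.13, 4.10 ± 0.13 and 4.21 ± 0.15. The exception was Dcn, the matrix proteoglycan decorin, singled out after its values were seen, which was high in both groups (8.68 ± 0.12 and 8.61 ± 0.19) and changed by -0.07 ± 0.13. The list lay above the other genes in limma's camera test (adjusted p = 5.19e-16), but not when its inter-gene correlation was estimated (adjusted p = 0.181 with an estimated correlation). The median change was 3.96 within slide 1 and 4.37 within slide 2, and the mean shift against other genes was 3.48, or 3.61 with slide as a block.

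Markers of macrophages and other leukocytes behaved alike. Of 15 measured, 12 rose and 0 fell (12 rises adjusted over the list alone), with a median of 4.35, or 3.44 with genes below background in the controls at their lower bound, and 1.81 under normexp. Ptprc, the leukocyte antigen CD45, rose at least 12.2-fold, the complement gene C1qc by 6.06 ± 0.39 and the lysozyme gene Lyz2 by 4.86 ± 0.34. Under normexp the log2 change of Ptprc was 1.81, less than its bound. The genes not called, named after their values were seen, were Csf1r (-0.51 ± 0.26), the macrophage growth factor receptor, Aif1 (0.08 ± 0.24) and the T cell gene Cd3e (-0.08 ± 0.13). By camera the list was higher (adjusted p = 4.16e-08; adjusted p = 0.215 with an estimated correlation), with a mean shift of 3.53 that became 3.61 with slide as a block, and with medians of 3.74 and 5.06 within slides 1 and 2.

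Genes of the epithelial-mesenchymal transition rose, and basal and myoepithelial markers rose in part, on the same arrays as the fibroblast list (median 4.06) and the macrophage list (median 4.35, or 3.44 with bounds). In the transition list 10 of 14 rose and 0 fell, 10 also when adjusted over the list alone (median 2.71, or 1.44 under normexp; camera adjusted p = 9.95e-08; adjusted p = 0.125 with an estimated correlation; slide medians 2.56 and 2.87). Vim, the intermediate filament of mesenchymal cells, rose by 3.34 ± 0.11, and the transcription factors Zeb1 and Snai1 by 3.86 ± 0.17 (2.48 under normexp) and 2.66 ± 0.13. Among basal and myoepithelial markers 6 of 11 rose and 2 fell, the same numbers as adjusted over the list alone (median 1.75, or 1.02 under normexp; camera adjusted p = 0.00429; adjusted p = 0.230 with an estimated correlation; slide medians 1.33 and 2.23). Cnn1, Tagln and Acta2, which encode actin-binding proteins and an actin of smooth muscle, rose by 4.04 ± 0.16, 3.31 ± 0.18 and 3.36 ± 0.23, while Krt17, a keratin of basal cells, fell (-1.83 ± 0.14).

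Luminal epithelial markers went the other way. Of 21 measured, 13 fell and 1 rose, or 14 and 1 adjusted over the list alone, with a median of -0.50. Krt18, Epcam and Cdh1, the last the adhesion molecule E-cadherin, changed by -0.95 ± 0.11, -0.76 ± 0.11 and -0.76 ± 0.11. The list lay below other genes by camera (adjusted p = 0.0170; adjusted p = 0.409 with an estimated correlation), with slide medians of -0.55 and -0.65 and a mean shift of -0.55, or -0.57 with slide as a block. With array weights the shift of -0.48 was not called (adjusted p = 0.0524). When arrays were scaled on the spike-ins, 3 of the 21 fell and 1 rose, and Epcam (-0.37) and Cdh1 (-0.37) were not called. On these arrays the fibroblast and macrophage lists were higher by medians of 4.06 and 4.35 (3.44 with bounds).

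Steroid receptors and progestin-responsive genes did not shift as a list (camera adjusted p = 0.790; 2 of 18 rose and 5 fell, and 2 and 4 adjusted over the list alone, but 5 and 1 under spike-in scaling). Besides Elf5, the glucocorticoid receptor gene Nr3c1 fell (-0.78 ± 0.15), and Cited1, a transcriptional co-activator, rose (3.11 ± 0.68). Pgr, the progesterone receptor, changed by -0.79 ± 0.20 (adjusted p = 0.0208), a call that ended with slide as a block (-0.62), under spike-in scaling (-0.40), without the filter on dim probes and without any single array other than pre-miR-16 replicate 2. A dimmer second probe for Pgr, looked at after the first results, fell further (-1.86), and the call held with the mean of both probes (-1.32, adjusted p = 6.19e-04). Nr3c1 was not called under spike-in scaling either (-0.39). Of 6 milk protein genes measured 2 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.440). Spp1, which encodes osteopontin, rose by 3.67 ± 0.44 and Muc15 changed by -2.50 ± 0.45 (-1.06 under normexp).

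The 2 targets recalled as named by this study both fell with arrays scaled on the 75th percentile. Named by the study itself, they are not independent evidence of a direction. The Ccnj probe lies on chromosome 19 from 40742196 to 40742255 and the Fubp1 probe on chromosome 3 from 152133578 to 152133637 (build mm7, per the file annotation). Ccnj was lower on each of the 3 pre-miR-16 arrays than on any control array, and stayed called under every alternative run, at between -2.07 and -0.99. Fubp1, which encodes a DNA-binding activator of Myc, fell from -2.17 ± 0.22 to -2.76 ± 0.15, a change of -0.58 ± 0.15 (adjusted p = 0.0178), with changes between -1.60 and -0.58 at its 3 probes. The Fubp1 call ended under spike-in scaling (-0.20, adjusted p = 0.438), with slide as a block (-0.54, adjusted p = 0.0857), without the filter on dim probes, and without pre-miR-Control replicate 2, pre-miR-16 replicate 1 or pre-miR-16 replicate 3. Transcripts of the genes that host miR-16, Dleu2 and Smc4, changed by -0.13 ± 0.20 and -0.23 ± 0.18 and were not called.

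Genes reported elsewhere as targets of the miR-16 family went both ways. Of 50 measured, 17 rose and 10 fell, or 18 and 11 adjusted over the list alone, and under spike-in scaling 20 rose and 0 fell. The median change was -0.01 and the mean 0.41, against a median of -0.20 over all genes. Camera likewise placed the list above other genes (adjusted p = 0.0170, or 0.215 with an estimated correlation). Those named by smallest p all rose: Reck (at least 3.12-fold, but a log2 change of 0.71 under normexp), Twist1 (3.04 ± 0.20, or 1.18 under normexp), Fgf7 (2.89 ± 0.24, or 1.12) and Ccnd2 (3.65 ± 0.31), a membrane protease inhibitor, a mesenchymal transcription factor, a fibroblast growth factor and a D-type cyclin. Twist1 and Fgf7 were well above background on 1 of 3 control arrays. Bcl2, the anti-apoptotic gene, fell (-0.84 ± 0.13, adjusted p = 0.00349) but was not called under spike-in scaling (-0.46). The fibroblast list, with its median of 4.06, rose on the same arrays.

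Some genes of G2/M and mitosis were higher in the pre-miR-16 cultures, unevenly between replicates, and fewer genes of G1/S were called. Of 33 genes of G2/M and mitosis, 16 rose, 0 fell and 17 were not called, with 16 rises also when adjusted over the list alone and a median of 1.32, or 0.86 under normexp (camera adjusted p = 9.95e-08, or 0.436 with an estimated correlation). Under spike-in scaling 26 rose and 0 fell, with a median of 1.71. Tpx2, a spindle assembly factor, rose by 2.45 ± 0.19, Ccnb1, the mitotic cyclin B1, by 1.52 ± 0.32 (0.78 under normexp) and Kif4, a chromosome-bound kinesin, by 1.72 ± 0.36. The list's median level was -0.51 on pre-miR-16 replicates 1 and 3 but -1.96 on replicate 2, against -2.95 to -2.36 on the controls. Its median change was therefore 1.51 within slide 1 and 0.43 within slide 2, and its mean shift of 1.31 became 0.94 with slide as a block. Of 35 genes of G1/S and DNA replication 5 rose and 3 fell, or 4 and 2 adjusted over the list alone, and 12 and 0 under spike-in scaling (median 0.29, or 0.67 under spike-in scaling; camera adjusted p = 0.0110; adjusted p = 0.672 with an estimated correlation). The ribonucleotide reductase gene Rrm2 rose by 3.01 ± 0.59 (1.84 under normexp) and Tyms, thymidylate synthase, by 0.97 ± 0.19. This list's shift was lost with slide as a block (0.17, adjusted p = 0.0650) and without pre-miR-16 replicate 1 (0.23) or replicate 3 (0.22), its slide medians were 0.47 and -0.24, and its median level was 0.42, -0.40 and 0.52 on pre-miR-16 replicates 1, 2 and 3 against 0.0493 to 0.0694 on the controls. The fibroblast and macrophage lists were higher on all 3 pre-miR-16 arrays than on the controls. Their median levels were highest on replicate 2 (3.54 and 1.22), against 3.23 and 0.61 on replicate 1 and 3.14 and 0.72 on replicate 3. The G2/M and G1/S lists were lowest on replicate 2 among these 3 arrays, so their order differed.

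Targets of p53 and inhibitors of cyclin-dependent kinases rose in part. Of 26 measured, 13 rose and 5 fell, also when adjusted over the list alone, and 14 and 1 under spike-in scaling (median 0.60; camera adjusted p = 2.22e-04; adjusted p = 0.215 with an estimated correlation; slide medians 0.66 and 0.78). Cdkn1a, the kinase inhibitor p21, rose from -0.23 ± 0.26 to 2.01 ± 0.23, a change of 2.24 ± 0.18 (adjusted p = 2.38e-04). Pmaip1, the pro-apoptotic Noxa, rose by 4.96 ± 0.26, Eda2r, a death receptor of the TNF family, at least 14-fold and the kinase inhibitor Cdkn1c at least 6.63-fold. Under normexp the log2 changes of Eda2r and Cdkn1c were 1.91 and 1.12, less than their bounds. The BCL2 family and caspases did not shift against other genes (camera adjusted p = 0.798; lower by fry, adjusted p = 0.0243; 3 of 22 rose and 8 fell, the same numbers as adjusted over the list alone, and 5 and 1 under spike-in scaling). Bik, a pro-apoptotic member, fell (-1.03 ± 0.11), and Birc2, an inhibitor of apoptosis, changed by -0.60 ± 0.09, or by -0.21 and not called under spike-in scaling. The fibroblast and macrophage lists, at medians of 4.06 and 4.35 (3.44 with bounds), moved on the same arrays.

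Many inflammatory and stress genes and 14 of 28 interferon response genes rose, on the same arrays as the macrophage list (median 4.35, or 3.44 with bounds) and the fibroblast list (median 4.06). Among NF-kB targets and inflammatory cytokines 16 of 24 rose and 0 fell, 16 also when adjusted over the list alone (median 2.18, or 1.05 under normexp; camera adjusted p = 5.39e-10; adjusted p = 0.144 with an estimated correlation; slide medians 1.78 and 2.51). Il6, the acute phase cytokine, rose from -5.08 ± 0.23 to -0.75 ± 0.27, a change of 4.33 ± 0.18 (adjusted p = 1.80e-05; 2.39 under normexp), and Csf1, the macrophage growth factor, rose by 3.93 ± 0.15. Of 28 interferon response genes 14 rose and 1 fell, or 15 and 1 adjusted over the list alone (median 0.54; camera adjusted p = 1.92e-05; adjusted p = 0.436 with an estimated correlation; slide medians 0.54 and 0.94). Isg15, a ubiquitin-like protein, rose by 3.70 ± 0.23, Ifi44 by 3.54 ± 0.20 and the interferon regulator Irf7 by 1.72 ± 0.19. Of 20 genes of endoplasmic reticulum stress and ATF4, 13 rose and 1 fell, or 17 and 1 adjusted over the list alone (median 0.69; camera adjusted p = 2.85e-08; adjusted p = 0.0690 with an estimated correlation; slide medians 0.69 and 0.67). The chaperone gene Hspa5 rose from 4.64 ± 0.08 to 5.68 ± 0.12, a change of 1.03 ± 0.10, the lipoprotein receptor gene Vldlr rose by 3.76 ± 0.09 and Psat1, of serine synthesis, by 1.04 ± 0.09.

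Of 22 cholesterol synthesis genes 10 rose, 0 fell and 12 were not called, or 8 and 0 adjusted over the list alone (median 0.57; camera adjusted p = 3.43e-05; adjusted p = 0.430 with an estimated correlation; slide medians 0.80 and 0.19). Stard4, which encodes a sterol transporter, rose at a probe that was not well above background on any control array (1.31 under normexp), and by 1.59 at its other probe. Nsdhl, of sterol synthesis, rose by 0.85 ± 0.15, with changes between -0.67 and 0.97 at its 4 probes. In the TGF-beta and SMAD list 11 of 22 rose and 6 fell, the same numbers as adjusted over the list alone, and 11 and 0 under spike-in scaling (median 0.16; camera adjusted p = 0.0170; adjusted p = 0.215 with an estimated correlation; slide medians 0.16 and 0.23). Ccn2, a matrix-related target of TGF-beta, rose by 3.42 ± 0.13, and the ligand gene Tgfb3 by 1.46 ± 0.11. This list's call ended with array weights and without pre-miR-16 replicate 2 (shift 0.35). The fibroblast list rose on the same arrays, with its median of 4.06.

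The remaining lists were not called by camera. In ERBB, PI3K and MAPK signalling 7 of 32 rose and 6 fell (7 and 5 adjusted over the list alone, 9 and 1 under spike-in scaling; camera adjusted p = 0.228), with Egfr, the epidermal growth factor receptor, up by 3.26 ± 0.18, Hbegf, one of its ligands, up by 1.33 ± 0.17 and the MAPK phosphatase gene Dusp4 down (-1.28 ± 0.16). Erbb2 itself, named outside the rule and after its values were seen because the cultures are ErbB-2 positive, changed by -0.02 ± 0.17 and was not called. In the WNT pathway 5 of 13 rose and 2 fell, also when adjusted over the list alone, and 5 and 0 under spike-in scaling (camera adjusted p = 0.0677). Lef1, a WNT-responsive transcription factor, rose by 3.64 ± 0.14 (2.15 under normexp) and Rspo1, a WNT agonist, at least 7.83-fold. Under normexp the log2 change of Rspo1 was 1.29, less than its bound. In hypoxia and glycolysis 6 of 20 rose and 2 fell (5 and 2 adjusted over the list alone, 8 and 1 under spike-in scaling; camera adjusted p = 0.114). Vegfa, the vascular growth factor, rose by 0.92 ± 0.09 and the prolyl hydroxylase gene Egln3 at least 3.94-fold. Under normexp the log2 change of Egln3 was 0.95, less than its bound. In the small RNA pathway 1 of 14 rose and 5 fell, also when adjusted over the list alone, and 4 and 0 under spike-in scaling (camera adjusted p = 0.928; lower by fry, adjusted p = 0.0280). Drosha, the nuclear microRNA processing enzyme, changed by -0.64 ± 0.11 and was not called under spike-in scaling (-0.26). Of 5 adipocyte markers 2 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.0737), namely Lpl, lipoprotein lipase, by 2.74 ± 0.20 and Fabp4 by 3.75 ± 0.91, whose call ended with slide as a block (3.13) and without pre-miR-Control replicate 1, pre-miR-16 replicate 1 or pre-miR-16 replicate 3. Only 4 of 11 endothelial markers were measured, too few for the list test, and 2 rose, also when adjusted over the list alone: Eng, a TGF-beta co-receptor, by 3.01 ± 0.20 and Robo4 at least 2.67-fold, the latter not called under normexp. Among 13 housekeeping genes Ppia rose (0.52 ± 0.12) and Ywhaz fell (-0.53 ± 0.14), also when adjusted over the list alone (camera adjusted p = 0.609), and neither call held in all settings.

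**Figure D2:**
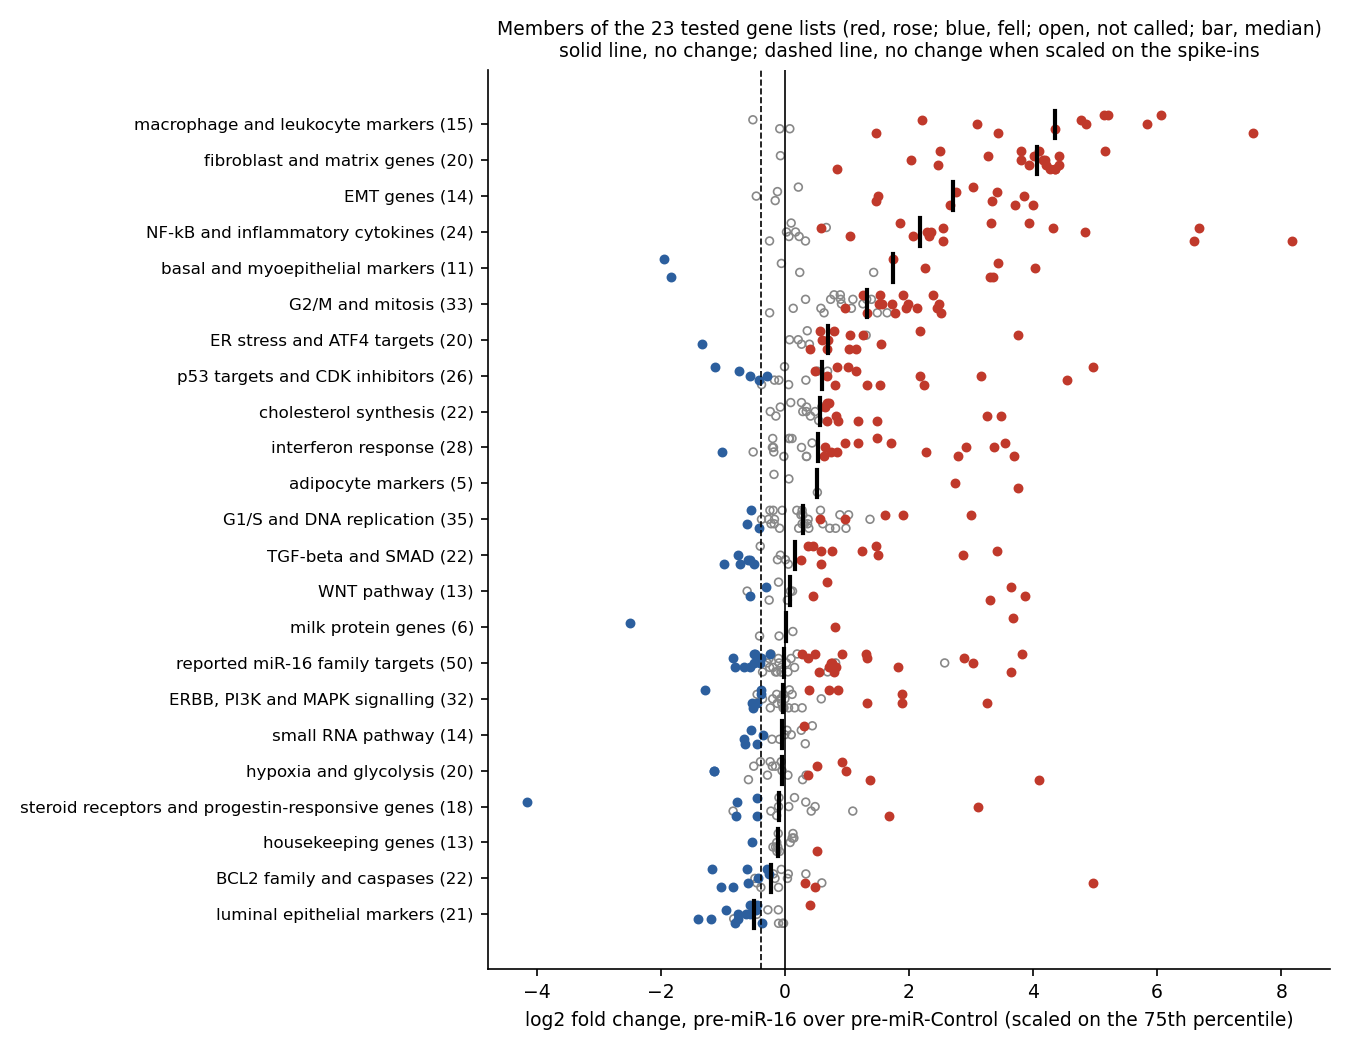
Log2 fold change of pre-miR-16 over pre-miR-Control (horizontal axis) for each measured member of the 23 tested gene lists (rows, number measured in brackets), in red where it rose, blue where it fell and open where it was not called, with the list's median as a bar. Medians run from -0.50 for luminal markers to 4.35 for macrophage and leukocyte markers, and the dashed line marks no change under spike-in scaling, 0.38 below the solid line. Genes below background in the controls are drawn at their printed change. With such genes at their bound the macrophage median was 3.44, below the 4.06 of the fibroblast list, and under normexp it was 1.81.

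In all, camera called 14 of the 23 lists with its preset correlation and 0 with an estimated correlation, where 5 lists had an unadjusted p under 0.05. Higher correlation alone does not account for this loss. For the ER stress and TGF-beta lists the estimates were -0.0234 and -0.0315, below the preset 0.01. Their unadjusted camera p still rose from 3.71e-09 to 0.00300 and from 0.0104 to 0.0479. When it estimates the correlation, camera also uses fewer degrees of freedom, limited by the number of arrays. Limma's fry, which tests whether a list's genes move on balance one way and does not compare it with other genes, called 16, among them the adipocyte and WNT lists, which were higher, but not G2/M and mitosis (adjusted p = 0.0708) or G1/S (adjusted p = 0.506). The BCL2 and small RNA lists, which fry placed lower, had medians of -0.22 and -0.04, against -0.20 over all genes.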

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

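Spike-in scaling, slide as a random block and the crossed replicate block were chosen only after the results were seen. Of the comparisons of gene lists across alternatives 454 kept direction and side of the threshold, 6 became weaker, 4 stronger and 18 changed sign, and for named genes these numbers were 2600, 63, 6 and 26. The number of changed genes, 8197, ran from 6009 with slide as a block to 10559 with array weights, apart from 4713 under spike-in scaling (of which 1041 fell) and 5417 with a fold of at least 1.5 required. It ran from 5700 to 9181 with single arrays left out, falls from 3599 to 5780, and for these the cause was not tested. Replicate number as a block gave 6529 and the crossed block 7137; arrays of the same number did not resemble each other (deviation correlations -0.0876, -0.0261 and -0.00284, or 0.0634, 0.0222 and -0.00284 by the matrix order), although those numbered 1 and those numbered 2 share a slide. Of 23 lists, 14 shifted by camera, 12 to 15 in most settings, 16 by fry and 0 with an estimated correlation. Signal over background limits the size of change for dim genes. The log2 change was over 1.5 times smaller for 36 of 107 called named genes with normexp and the 75th percentile. It was so for 35 with normexp and quantile normalization, 35 with the deposited series matrix values and 17 under spike-in scaling. The seed-site test in 3' UTRs was not run, and slide as a random block gave no list tests.

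Results that changed sign were none of them called, and the cause was not tested. The shift of the list: BCL2 family and caspases (-0.05) became 0.0825 with normexp and the 75th percentile, 0.0774 with normexp and quantile, 0.0795 with the series matrix, 0.0359 with no filter and 0.11 with all 6 arrays above background, and ran from -0.0890 to 0.00564 with single arrays left out. That of the list: steroid receptors and progestin-responsive genes (-0.07) became 0.0704, 0.0490, 0.0509, 0.16 and 0.27 in the same settings and 0.0868 with array weights, and ran from -0.18 to 0.14. That of the list: housekeeping genes (-0.07) became 0.0284, 0.0240, 0.0341, 0.0175 and 0.0296. Spike-in scaling, which raises every value, gave Rpl13a 0.23, Rplp0 0.25, B2m 0.27, Tbp 0.28, Tfrc 0.30, Actb 0.26, Smc4 0.16, Dleu2 0.25, Retn 0.21, Egfl7 0.12 and Esam 0.14. Rplp0 was 0.0831 with quantile, 0.0553 with normexp and quantile and 0.0517 with the series matrix. Gusb was -0.00278 with median centring and -0.11 with the mean of its probes, Tfrc 0.13 and Dleu2 0.0686 with array weights, and Actb 0.22 with slide as a block. With single arrays left out Hprt ran from -0.0264 to 0.37, Tfrc from -0.21 to 0.14, Actb from -0.45 to 0.13, Dleu2 from -0.23 to 0.0565, Retn from -0.29 to 9.14e-04 and Esam from -0.50 to 0.0491.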

Other observations

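Acute phase genes rose in the pre-miR-16 cultures, on the same arrays as the macrophage list (median 4.35, or 3.44 with bounds) and the fibroblast list (median 4.06). In a list of 16, written after Saa1, Saa2, Saa3 and Lcn2 had been seen, 11 of 12 measured rose and 0 fell (median 2.78). Of the other 8 measured 7 rose and 0 fell (median 1.74; camera adjusted p = 2.51e-06; adjusted p = 0.0569 with an estimated correlation). Lcn2, an iron-binding defence protein, rose by 3.32 ± 0.21, Hp, haptoglobin, by 2.24 ± 0.29, C3, a complement protein, by 1.79 ± 0.13, and Serpina3g, a protease inhibitor, at least 5.46-fold. The list's median level was 6.27 and 6.15 on pre-miR-16 replicates 1 and 3, 2.12 on replicate 2 and -0.69 to -0.63 on the controls. The macrophage and fibroblast lists were instead highest on replicate 2 (1.22 and 3.54), against 0.61 and 3.23 on replicate 1 and 0.72 and 3.14 on replicate 3. Replicate 2 also stood apart along the second principal component (44.7 against -19.7 and -24.0), which held 7.78% of the variance where the first, between the groups, held 83.7%. Lysosomal genes, some of them abundant in macrophages, shifted less on these arrays, with 8 of 24 up and 5 down, or 9 and 5 adjusted over the list alone (median 0.15; camera adjusted p = 0.0128; adjusted p = 0.382 with an estimated correlation), among them Ctsk, an osteoclast protease, by 4.21 ± 0.31 and Psap by 1.80 ± 0.11. Lists not called were keratinisation (3 of 20 rose, 6 fell; camera adjusted p = 0.851), ribosomal proteins (0 of 33 rose and 2 fell, or 0 and 0 adjusted over the list alone; camera adjusted p = 0.553), oxidative phosphorylation (1 of 32 rose and 4 fell, or 0 and 0 adjusted over the list alone; camera adjusted p = 0.538) and a second endothelial and pericyte list (2 of 7 rose, 2 fell; camera adjusted p = 0.851), and of 4 lymphocyte and mast cell markers, too few to test, 1 rose and 1 fell.

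The tests of array scaling, slides, Ccnj and Fubp1 below were chosen only after the results were seen; those of the seed match and the splits were written before their values, and those of the second lists after the first results but before these lists' medians. A hypothesis for the rise of macrophage and fibroblast genes is that the pre-miR-16 cultures held more of these cells, although per the labels fibroblasts had been removed by sedimentation. Second lists of such genes rose too: 24 of 28 leukocyte genes (median 3.94, or 3.49 with genes below background at their bound), with Mpeg1 at 5.03 ± 0.32 and Ctss at 4.18 ± 0.35, and 21 of 25 fibroblast genes with 1 called fall (median 3.36, bounded 3.09, or 3.16 without 3 genes that earlier lists hold), with Fbln5 at 4.09 ± 0.13 and Tnc at 3.95 ± 0.13, which is in line with more such cells. Of the 30 genes in each list, 2 leukocyte genes (Spi1 and Ikzf1) and 5 fibroblast genes had probes of which none was kept. A gene could be kept through the pre-miR-16 arrays alone, which favours rises. Among those measured, 5 leukocyte and 4 fibroblast genes were not well above background on any control array. Camera called both second lists, leukocyte and fibroblast, with its preset correlation (adjusted p = 1.28e-14 and 4.37e-15). It called neither with an estimated correlation (adjusted p = 0.273 and 0.124). Against array scaling and slides as the source of the rise, the largest spike-in difference was -0.59 and the smallest within-slide macrophage median 3.74. Csf1r, Dcn, Lcp1 (-0.29) and Vav1 (-0.57), singled out after their values were seen, did not rise, while Cdh11 was called as fallen at its brightest probe (-1.12) and its 3 probes ran from -1.12 to 4.17. Whether cells were gained, or the tumour cells changed their transcription, stays open, as no cell counts were analysed here.

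A hypothesis for the falls of Ccnj and Fubp1 is that a lower share of epithelial cells lowered their RNA. Ccnj lay 3.52 SDs below the median change of the luminal markers, of which the lowest changed by -1.40. Under normexp with quantile normalization the -0.99 of Ccnj compares with a luminal median of -0.49. But under normexp with the 75th percentile Ccnj changed by -1.07, and the luminal keratins Krt8 and Krt18 by -1.18 and -0.95. The distance depends on the background correction for this dim gene, so whether that share alone lowered Ccnj stays open. Fubp1 lay 0.191 SDs below the luminal median at its brightest probe, so its fall there could follow the share of epithelial cells. That probe (-0.58) changed least of its 3 probes, of which another fell further (-1.60), and the others were not tested in this way. Both genes are recalled as named by the study, so neither is independent evidence of a direction.

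A hypothesis that miR-16 lowered its targets at large was tested by the seed match in the 60-base probes: 120 genes with it lay at percentile 84.2 of 8466 heptamers, with a mean GC-adjusted change of 0.13 (SE 0.11) against -0.21 at the 5th percentile (33 fell and 19 rose, against 5533 and 2664 of all 16702 genes). The probes hold only a small part of each 3' UTR, so this may say little of repression through sites elsewhere. Among the 10 splits of the 6 arrays, too few for a share under 0.05, the real one gave the most changed genes (8197, highest other 0) and shifted lists (14, highest other 12), that is 1 of 10 for each. Each other split has arrays of both groups on each side, so the group difference adds to its spread and holds its gene calls down. The gene counts therefore decide little, and the list count set the real split apart by little.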
